A study of Mus musculus with 2 samples.

How the data were processed

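Primary chondrocytes were isolated from the knee cartilage of mice at postnatal day 3, grown to confluence and exposed to recombinant human BMP-2, a growth factor that drives cartilage and bone formation, at 100 ng/ml for 24 hours, per the labels' protocols. Methylated DNA was captured with the MBD2 protein from genomic DNA sheared to about 300 bp, and the captured DNA was sequenced (MBD-seq). There was 1 library from Control cells and 1 from Uhrf1 conditional knockout (cKO) cells, so no value has a replicate and no p-value of a group difference was computed.

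The deposited data are a single list of regions in which the Control library exceeded the cKO library. Per the file headers, the authors called the regions with MACS 1.4.2, with the Control library as the enriched file and the cKO library in the place of the background, at a p limit of 1e-10, with an effective genome size of 1870 Mb, a band width of 300 bp and a regional background over 1000 and 10000 bp. Per the file headers, at most 1 tag was kept per position, the larger library was scaled towards the smaller one, the tag size was 55 bp and the modelled fragment shift d was 58 bp. This d is close to the tag size and far below the sheared length of about 300 bp. Its effect on region lengths, summits and folds was not examined. The build was mm10, per the submitters' processing notes. The aligner, and the way in which reads matching several places were treated, are not given in the sources used here.

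Each region carries the authors' values. The tag count is the whole number of Control tags in the region after duplicate removal, as deposited, without scaling. The score is minus 10 times the log10 of the authors' Poisson p, per the file headers. The fold is the ratio of Control tags at the summit to the local background expected from the cKO library, as the authors' caller gave it. The FDR is a percent value of the authors' caller: the number of regions found with the libraries swapped, relative to the number found as listed, at the same p or better, limited to 100. The cKO tags of a region were not used here, so a fold could not be recomputed. The fold, score and FDR belong to the authors and served only to describe, rank or filter regions within the list.

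Per the file headers, the Control library held 21831989 tags, of which 9782276 were kept (44.8%), and the cKO library held 19760028 tags, of which 15039206 were kept (76.1%). The precision of any region is limited by its tag count, which ran from 11 to 6918. Counting intervals (95%, Wilson for shares and exact Poisson for counts of regions) cover counting error only.

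Genes were taken from the RefSeq gene table of GRCm38.p6, the assembly that mm10 names, with 21887 protein-coding genes among 49943 gene models on 21 chromosomes. The table gives each gene's start and end without strand, exons or sequence. The planned promoter share was therefore computed as the share of region summits within 1 kb of either end of a protein-coding gene, which mixes transcription starts with transcript ends, and the planned 5 kb upstream of a gene became 5 kb on both sides. Exon, intron and UTR classes, CpG density, repeat content and a background matched on CpG density need a genome sequence or exon models and were not analysed here. MBD2 captures DNA rich in methylated CpG, so a background not matched on CpG differs from what capture could reach.

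Random region sets (1000) kept each region's length and chromosome and placed its summit uniformly between the first and the last annotated gene or region of the chromosome. For each of 16 gene lists, the share of genes with a region was set beside 10000 random lists of the same size, matched on biotype class and gene length in 10 groups. The plan matched gene-end shares on promoter CpG count instead, which needs sequence. The ranges given are the central 95% of these sets, which describe placement and gene choice in this pair of libraries and are not replicate error. The lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Uhrf1 and Hspb1, the 20 protein-coding genes with the largest fold at a gene end, the 10 with the most regions per kb among those with at least 5 regions, the 5 with the most regions, and up to 4 members of each list with a region at an end by fold, or else up to 2 with a region in the gene or within 5 kb. Gene models named Gm with digits or ending in Rik were not named. All listed symbols were matched to the table, by symbol or by a synonym belonging to a single gene.

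The alternatives were stricter limits on p (1e-15, 1e-20), an FDR of at most 5%, joined regions, other overlap rules, other windows around gene ends, and gene bodies alone. Random placement within 500 kb of each region (100 sets), random lists matched on gene density as well, and the FDR limit for most results were added after the data were seen. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The functions were tested on simulated data. A planted gene-end share of 7.92% among 35861 simulated regions was recovered as 7.87%. Of 200 unchanged lists of 20 genes, 2% fell outside the range of the random lists, and 99% of lists in which 70% of the genes were given a region were found above it. These lists were drawn gene by gene over uniformly placed regions. Neither rate therefore covers clustered regions, genes that share regions or smaller effects. The count of swapped-library regions implied by a simulated FDR column was within 2 of the true count at each of 15069 scores. That column was built with the same formula, so this checks the computation and the rounding, not how the authors' column was made.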

Results

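The series compared methylated DNA captured by MBD2 between Control primary mouse chondrocytes and those with a conditional knockout of Uhrf1. Uhrf1 is a ubiquitin ligase that recognises hemimethylated DNA and brings the maintenance methyltransferase Dnmt1 to replicating DNA. Control and Uhrf1 conditional knockout (cKO) cells, both treated with BMP-2, were represented by 1 library each, of 9782276 and 15039206 kept tags. Duplicate removal discarded 55.2% of the Control tags and 23.9% of the cKO tags. The folds, scores and FDR values given for regions are the regions' own values in the authors' deposited table. All regions described here carried more Control than cKO signal in that list. Regions with more cKO signal were not listed, and only their number, as implied by the FDR values, was examined. No difference between the genotypes has a replicate check.

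Uhrf1, the targeted gene (chromosome 17, 56303337 to 56323486, mm10), held 5 regions with more Control signal, and Hspb1, which encodes a small heat shock protein and was singled out by the study, had 2 regions beside it. The Uhrf1 regions spanned 9.38 kb within the annotated gene, and their folds in the authors' deposited table ran from 7.32 to 24.59. The authors' FDR was at most 0.74% for 4 of them and 100% for the region at 56311880 to 56312392, which had 65 Control tags. Uhrf1 ranked 6 by regions per kb of gene span among 962 protein-coding genes with at least 5 regions, gene models named Gm with digits or ending in Rik left out. The Hspb1 regions lay 238 bp and 2029 bp outside the annotated span (chromosome 5, 135887919 to 135889563). The nearer one, at 135886951 to 135887681, had 187 Control tags, a 10.06-fold excess and an FDR of 0.05%. The farther one, at 135885429 to 135885890, had 70 tags, an 11.08-fold excess and an FDR of 6.84%. As the Uhrf1 gene was itself targeted, a lower cKO signal within it can come from fewer copies of the DNA as well as from less methylation.

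**Figure D1:**
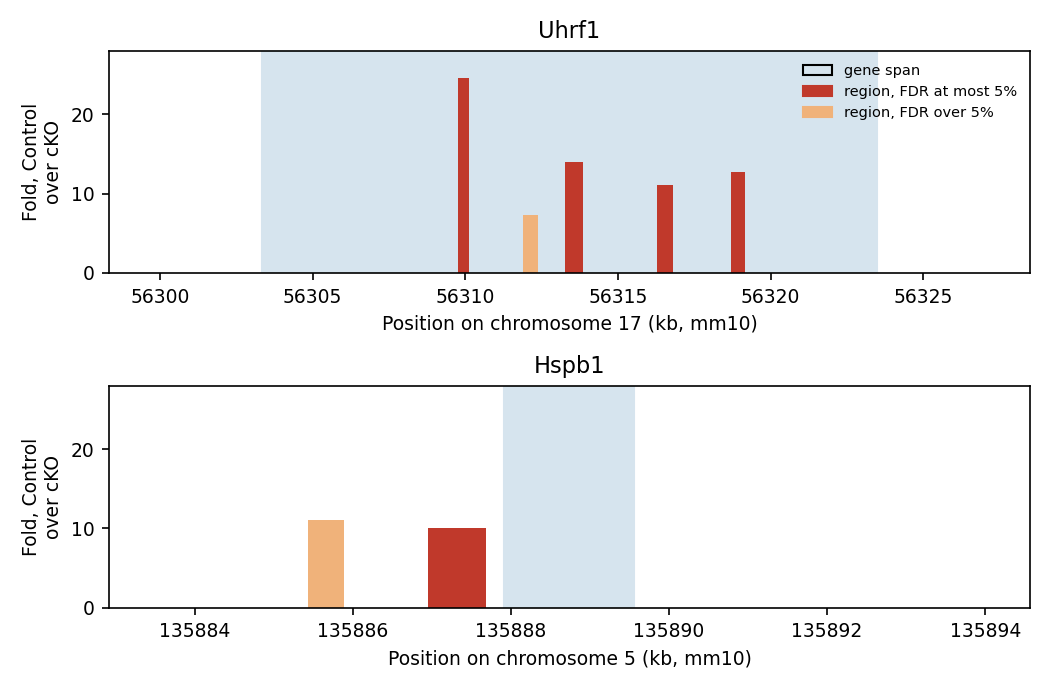
Regions with more Control than cKO signal at Uhrf1 (top) and Hspb1 (bottom), with 5 kb on either side of the annotated gene (pale blue). Bars give the authors' fold of Control over local cKO background against the position in kb on mm10, in red for an FDR of at most 5% and in orange above it. Uhrf1 holds 5 regions inside the gene, 4 of them red, and both Hspb1 regions lie outside the gene on the same side.

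Across the genome, 35861 regions with more Control signal covered 17.04 Mb, or 0.63% of the 2703 Mb between the outermost annotated genes and regions of the 21 chromosomes. They held 4573966 Control tags, 46.8% of those kept. The median region was 475 bp long (interquartile range 380 to 571) with 103 Control tags (59 to 175), and its fold was 12.18 (8.55 to 18.3). A fold of at least 10 was listed for 23160 regions (64.6%), and a fold of at least 50 for 586. The region with the largest fold, 161.5 with 161 Control tags, lay within Jade1 on chromosome 3 at 41560147 to 41560729. Jade1 encodes a chromatin-associated PHD finger protein. Such a fold depends on how low the cKO background was, which was not examined here. The few regions at the very top by tag count had small folds, whereas the highest tag quartile (8965 regions) had a median fold of 13.1. A 4049 bp region on chromosome 14 at 19415688 to 19419736 held 6918 tags at 3.26-fold. One on chromosome 2 at 98666229 to 98667359 held 1787 tags at 2.15-fold, the lowest fold in the list. It lay 1035 kb from the nearest protein-coding gene, Lrrc4c. At most 1 tag was kept per position, which limits the tag count of such dense regions and so their fold. Whether they lie in repeats was not examined. Of all regions, 20392 (56.9%) had an FDR of at most 5% in the authors' deposited table, with a median of 161 tags, and 5816 (16.2%) had an FDR of 100%, with a median of 42 tags. Regions limited to an FDR of at most 5% covered 11.21 Mb.

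The autosomes carried more regions per Mb than either sex chromosome. Chromosome 19 had 19.48 regions per Mb (95% counting interval 18.36 to 20.65) and chromosome 11 had 19.21, whereas chromosome 14 had 10.59 (10.03 to 11.18). The X chromosome had 4.998 (4.67 to 5.34), which was 0.36 times the median autosome (0.34 to 0.38). The Y chromosome had 3.66 (3.27 to 4.07). The median fold differed little between autosomes (11.52 to 12.48), was 13.0 on X and was 26.1 on Y, where the median region had 32 tags against 104 on autosomes. Across the 19 autosomes, regions per Mb rose with protein-coding genes per Mb (Pearson r = 0.59, 2-sided permutation p = 0.0104). The Spearman rho was 0.63 (2-sided permutation p = 0.00466). Both p-values concern the same relation and were not adjusted. Pearson r was 0.75 without the 2 autosomes farthest from the median gene density. Chromosomes are not replicates of the genotypes. The labels do not give the sex of the cells, so the copy number of X and Y is not known. X regions had a median of 78 tags. Neither copy number nor how well reads can be placed was matched, so these densities do not measure methylation loss.

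**Figure D2:**
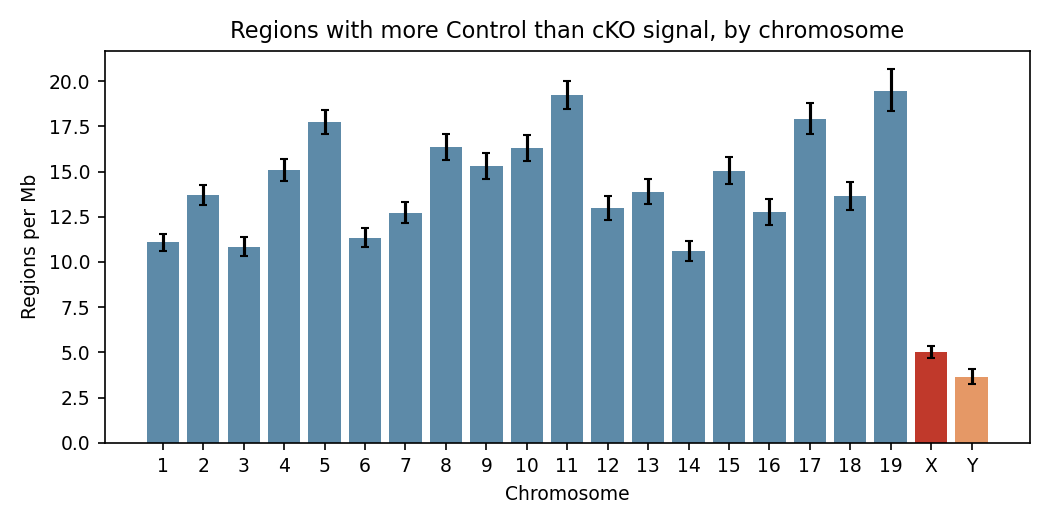
Regions with more Control than cKO signal per Mb of each chromosome, with 95% exact Poisson intervals that cover counting error only. Autosomes (blue) lie between 10.59 and 19.48 regions per Mb, X (red) at 4.998 and Y (orange) at 3.66.

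Regions lay mainly within protein-coding genes. The summit of 18660 regions (52.0%, 95% Wilson interval 51.5 to 52.6) fell within a protein-coding gene away from its ends, against 38.3% of randomly placed summits (37.8 to 38.8 over 1000 random sets). A further 1694 summits (4.72%, 4.51 to 4.95) lay within 1 kb of either end of a protein-coding gene, against 3.09% (2.92 to 3.28), a ratio of 1.53. Other gene models such as long noncoding RNAs and pseudogenes took 2727 summits (7.60%, against 8.02%), and 12780 (35.6%) were intergenic, against 50.6%. When each summit was instead placed at random within 500 kb of its own position, the ratio for gene ends was 1.04 and the random share within genes was 47.4%, so most of the excess at gene ends was shared with the surrounding sequence. The authors' fold was nearly the same in each class, with medians of 12.12 at gene ends, 11.99 within genes, 12.21 in other gene models and 12.41 in intergenic sequence. Of the 21887 protein-coding genes, 8350 (38.2%) overlapped a region, 2109 (9.64%) had one within 1 kb of an end, and 972 held 5 or more.

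Among genes with a region at an end, the largest folds belonged to genes of varied function. Ythdf1, which encodes a reader of N6-methyladenosine in RNA, led with 112.06-fold and 70 Control tags (chromosome 2, 180904318 to 180904679). Signalling genes in this group were Map3k4, a MAP kinase kinase kinase (95.58-fold, 89 tags), Bcl10, an adaptor of NF-kappaB signalling (84.87-fold, 145 tags), and Sgk1, a glucocorticoid-induced kinase (84.55-fold, 85 tags). Genes for transport, metabolism and matrix modification were Gusb, the lysosomal beta-glucuronidase (80.67-fold, 99 tags), Clcn6, an endosomal chloride transporter (70.68-fold, 43 tags), Chst1, a carbohydrate sulfotransferase (58.41-fold, 111 tags), and Slc2a1, the glucose transporter GLUT1 (56.3-fold, 110 tags). Transcriptional regulators were Jade1 (84.24-fold, 241 tags), Hoxc9, a homeobox gene (66.27-fold, 72 tags), Creb3l1, a membrane-bound transcription factor (62.62-fold, 32 tags), and Supt6, an elongation factor (59.67-fold, 117 tags). The remaining members of the 20 were Morf4l2, Ube3b, Tmem101, Qtrt2, Leng8, Leng9, Fndc9 and Zswim6, at 57.43-fold to 93.89-fold, with Leng8 and Leng9 sharing the same region. The authors' FDR was at most 2.93% for all 20. The fold divides by the local cKO background, so it can be large in a region with few tags, and it is large wherever that background is low. The same fold of 112.06 was listed for the Ythdf1 region with 70 tags and for a chromosome 10 region with 136 tags. Whether the background of these regions stood at its lowest possible value was not tested, so the largest folds do not rank the loss of methylation.

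Some genes held many regions. Wwox, a tumour suppressor in a large gene on chromosome 8, held 55, Zfhx3, a zinc finger homeobox gene on the same chromosome, held 50, Tenm3 held 37, Foxn3 held 30 and Tshz2 held 29. These genes are between 374 and 1297 kb long, and all had fewer than 0.1 regions per kb. Relative to length, the receptor gene Ifngr2, which encodes a subunit of the interferon gamma receptor, led with 0.35 regions per kb (6 regions), and the densest genes also included Tmem50a (0.35), the chemokine receptor gene Ccr4 (0.33), Sumf2 (0.29), Uhrf1 (0.25), Setd4, Mfsd1, F11r and Otud3. The 10 densest 1 Mb windows held 63 to 76 regions, against a median of 9 per window, and 3 of them lay on chromosome 5. The densest, at 115000001 to 116000000 of chromosome 5, held 76 regions, of which 27 overlapped Cit, a kinase of cell division. In all, 285 of 2714 windows (10.5%) held more than 30 regions, a limit set from windows of randomly placed regions, and these windows held 32.0% of all regions.

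Genes of the cartilage and growth plate carried regions about as often as random genes of the same length. Of 20 cartilage matrix and chondrocyte identity genes, 10 had a region in the gene or within 5 kb (50%, random median 55%, range 35 to 75) and none had one within 1 kb of an end. Examples were Sox5, a chondrogenic transcription factor with 20 regions in its span, and Sox6 (26.37-fold, FDR 82.79%). Sox5 is a long gene (143828425 to 144782287) on chromosome 6, which had 11.35 regions per Mb, and its largest fold, 49.44, came from a region of 37 tags. Of 20 hypertrophy and ossification genes, 10 had a region nearby and 4 had one at an end (20%, random median 10%, range 0 to 25). Those 4 were Sp7, an osteoblast transcription factor (11.51-fold, FDR 49.04%), Dlx5 (10.93-fold), Runx3 (8.12-fold) and Pth1r, the receptor for parathyroid hormone and its related peptide (7.92-fold), and the latter 3 had an FDR of at most 0.78%. Of 27 BMP and TGF-beta signalling genes, 16 had a region nearby, among them Bmpr1a at an end (18.56-fold) and Tgfbr2 (14.53-fold). Of 23 growth plate signalling genes, 16 had a region nearby, with Igf1r, the insulin-like growth factor 1 receptor gene, at 14.98-fold, Fgf18 at 12.4-fold and Lrp5 at 9.95-fold at an end. Of 24 limb patterning genes, 13 had a region nearby, with Msx2 (10.9-fold) and Meis2 (6.17-fold) at an end. Each of these shares lay within the range of the random lists.

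Imprinted genes and germline genes stood above random genes at gene ends, although for imprinted genes this depended on how shared regions were counted. A region can be listed only where MBD2 captured Control DNA, and the random genes were not matched on methylation in Control. An excess can thus reflect where Control DNA was methylated, and does not show a greater loss in cKO. Of 27 germline genes known to be methylated in somatic cells, 8 had a region within 1 kb of an end (29.6%, random median 11.1%, range 0 to 22.2), whereas 15 had one in the gene or within 5 kb (55.6%, the same as the random median). They included Tdrd9, a piRNA pathway helicase (30.34-fold, FDR 9.23%), Tex11, an X-linked meiotic gene (19.27-fold), Dazl, a germ cell RNA-binding protein (13.98-fold), and Dpep3 (12.49-fold). Without regions over an FDR of 5%, 6 of the 27 remained (22.2%, random median 7.41%), still above the range, whereas with a 2 kb window the share was the same but lay inside the range, at percentile 94.2. Of 28 imprinted genes, 7 had a region at an end (25%, random median 10.7%, range 0 to 21.4), and 18 had one in the gene or within 5 kb (64.3%, random median 50%, range 32.1 to 67.9). The 7 rest on 6 regions, and 6 genes would lie at the upper limit of the range and not above it. They included Igf2r, which clears insulin-like growth factor 2 (16.16-fold), Inpp5f (9.3-fold), and Sgce and Peg10 (9.06-fold), neighbours that shared 1 region. With an FDR of at most 5% the count at ends was 5, which lay within the range at percentile 98.3, whereas the count within 5 kb, 16 (57.1%, random median 35.7%, range 21.4 to 53.6), lay above it, but 14 with genes that share a region counted once (50%) did not. Of 20 genes of the DNA methylation machinery, 17 had a region in the gene or nearby (85%, random median 60%, range 40 to 80), and 4 had one at an end: Zbtb4 (34.09-fold, FDR 21.2%), Dnmt1, the maintenance methyltransferase (14.95-fold, FDR 0%), and Dnmt3a and Usp7, both with an FDR of 100%. The 17 include the targeted gene Uhrf1, and without it 16 of 19 (84.2%) lay at the upper limit of the range and not above it. The excess also did not hold with lists matched on gene density (range 45 to 85), at a p of at most 1e-15 (percentile 79.4) or with an FDR of at most 5%, where 11 of the 20 had a region against a random median of 45%.

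Small heat shock genes had 3 of 10 members with a region at an end (30%, the upper limit of the random range): Hspb9 (12.5-fold, FDR 51.42%), Hspb6 (11.59-fold) and Hspb1 (10.06-fold). As the study picked Hspb1 from these libraries, this list is not independent evidence. Olfactory and vomeronasal receptor genes had few regions: 74 of 1463 (5.06%) had one in the gene or within 5 kb, against a random median of 15.0% (13.7 to 16.5), and 15 had one at an end (1.03% against 4.44%). Olfr414 had the largest fold among the latter, 46.14. The random lists could draw these receptor genes themselves. Of 57 clustered protocadherin genes, whose annotated spans overlap, 24 had a region (42.1%, against 57.9%, range 47.4 to 68.4) and 1 had one at an end, Pcdhga8 (9.26-fold). Only 3 regions carry these 24 genes, so the random range, which draws genes singly, is not a fair measure for this list. The lower share near protocadherin genes did not hold with an FDR of at most 5%, at percentile 27.1. Markers of other cell types were within the random range. A region in the gene or nearby was found for 7 of 15 fibroblast, synovium and tendon genes, such as Col5a1 (28.89-fold, FDR 100%) and Pdgfra (20.03-fold), 8 of 15 blood cell genes, with Tal1 (8.36-fold, FDR 51.39%) and Csf1r (7.07-fold, FDR 14.61%) at an end, 8 of 12 endothelial genes, with Esam (7.24-fold, FDR 75.16%), and 4 of 12 skeletal muscle genes, with Myh3 (6.95-fold, FDR 100%). Of 20 housekeeping genes, 9 had a region nearby, and Gusb, Rplp0 (11.54-fold) and Actb (6.39-fold, FDR 7.49%) had one at an end. Over both measures, 7 of 32 shares lay outside the random range, or 5 of 30 without the protocadherins, and these 5 include the imprinted and methylation machinery shares, which depend on single genes or shared regions.

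**Figure D3:**
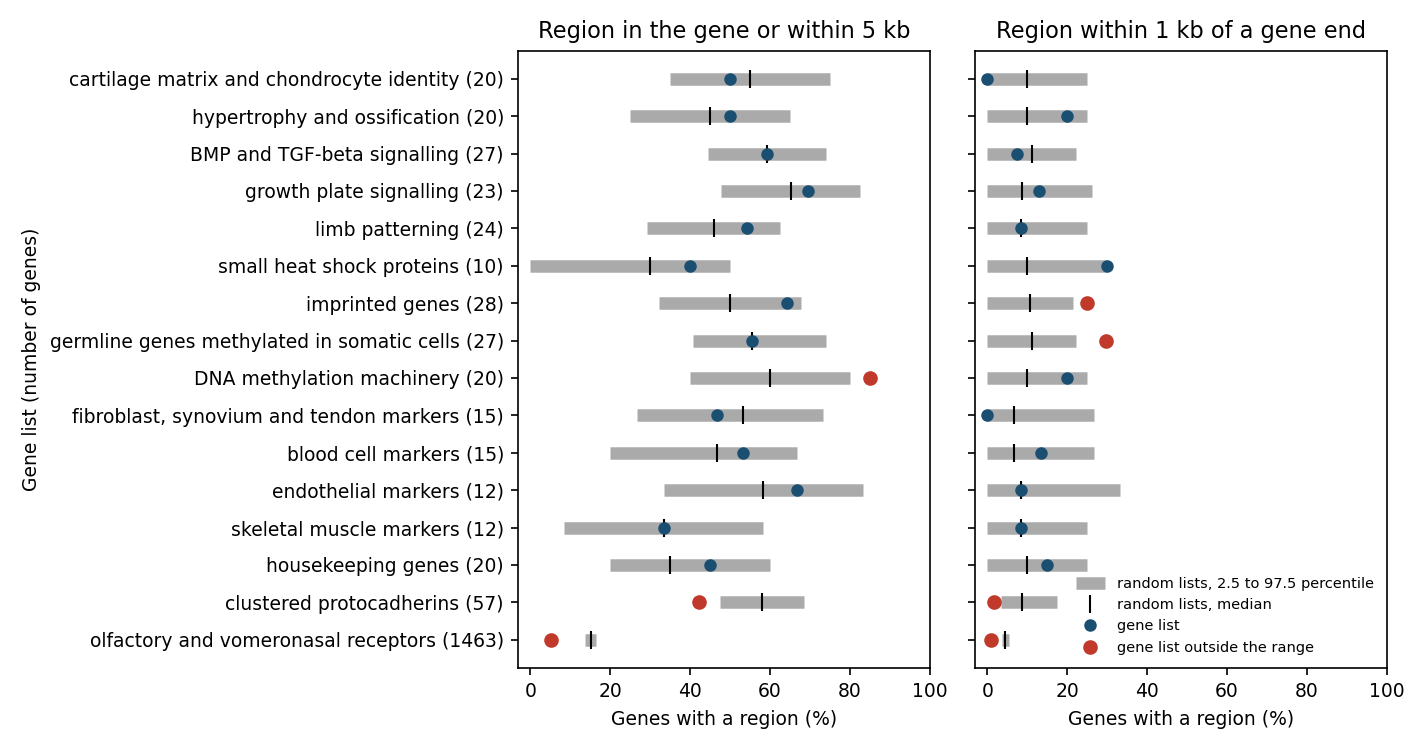
Percent of the genes of each list with a region in the gene or within 5 kb (left) or within 1 kb of either gene end (right). Points are the lists, in red where outside the central 95% of 10000 random lists matched on gene length (grey bars, with the median as a black tick). Germline (29.6%) and imprinted (25%) genes lie above the range at gene ends, and olfactory and vomeronasal receptors (5.06% and 1.03%) lie below it in both panels.

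The balance of the directions followed from the FDR column, since the caller's FDR compares the listed regions with those found after swapping the libraries. At a score of at least 500, 13219 regions were listed and the FDR implied 4 with more cKO signal. At a score of at least 300 the numbers were 19717 and 735, and at a score of at least 200 they were 25400 and 8865. Stronger regions thus lay almost entirely on the side of higher Control signal, and the ratio of listed to implied regions fell with the score. With 1 library per genotype, this balance cannot be told apart from a difference between the libraries themselves. Duplicate removal, for example, discarded 55.2% of the Control tags and 23.9% of the cKO tags. Rounding of the FDR alone leaves these counts uncertain by less than 2 regions. The counts also rest on this reading of the FDR, as the swapped regions themselves were not among the data used here.

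**Figure D4:**
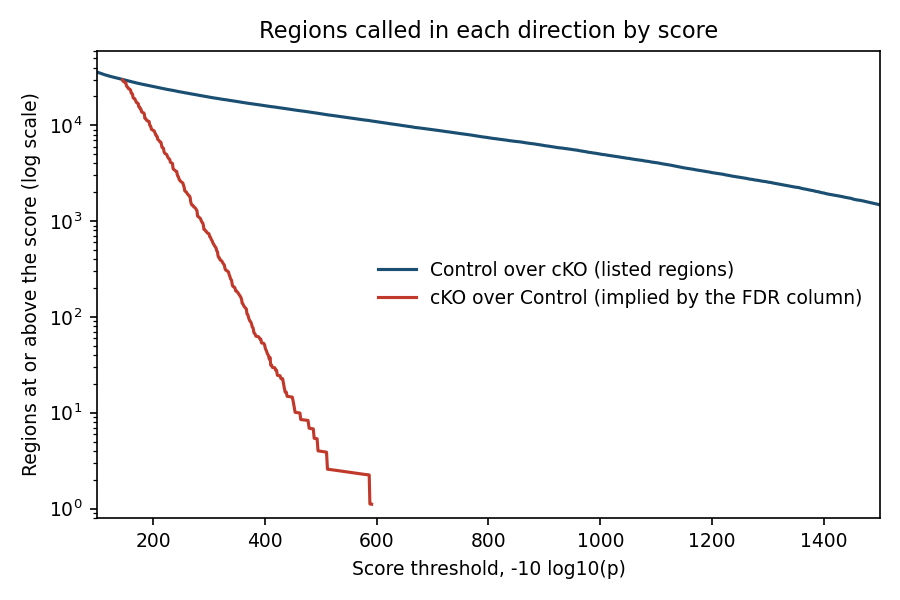
Number of regions at or above each score (log axis) against the score, minus 10 times log10 of the authors' p. The blue line counts listed regions with more Control signal and the red line counts regions with more cKO signal implied by the FDR column, drawn where the FDR lies between 0 and 100%. At a score of at least 200 the lines stand at 25400 and 8865.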

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

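The tests in this part were chosen after the values were seen. At the lowest score at which the FDR stayed under 100%, 145.13, the FDR column implied 29699 regions with more cKO than Control signal, beside 30045 listed regions with more Control signal. This was marked because it is a signal outside the region list itself, in a direction that the list does not show. Below that score the FDR was 100% for 5816 listed regions, so at least as many regions were found with the libraries swapped as were listed. An FDR read in this way is not an error rate, since a swapped call between genotypes can be a real gain in cKO as well as noise.

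Between an FDR of 5% and of 100%, the implied number of cKO regions grew by 28657. Of that growth, 74.8% came in 84 steps of 50 or more between neighbouring listed scores. The largest step held 966 regions, at a score of 164.07. A step can hold swapped regions of several scores lying in between. Repeated p-values arise where few tags meet the lowest possible background, so most of the weak cKO regions may be thin stretches that are empty in the Control library. Of 9653 listed regions in the same score range, 2282 (23.6%) shared their score with at least 9 others. These had a median of 38 tags, against 77 for the rest. They lie in the opposite direction, and the tags of the swapped regions themselves were not seen. The larger number of kept cKO tags, 1.54 times the Control number, cannot be told apart from genotype, because each genotype has 1 library. A gain of methylation at some sites in cKO cells stays open and was not tested.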

How the results depend on the processing

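With no replicates, depth and tag number limit each region, and no setting tests the genotype difference itself. The number of regions, 35861, was 20392 with an FDR of at most 5% and 17940 with a fold of at least the median, and ranged from 25400 to 35529 under the other alternatives. The covered length, 17.04 Mb, was 11.21 Mb and 8.12 Mb under the same 2 settings, which hold fewer regions by construction. The X chromosome density relative to autosomes, 0.36, was 0.33 at a p of at most 1e-20 and 0.31 at an FDR of at most 5%. The gene-end share relative to random placement, 1.53, was 1.63 at an FDR of at most 5% and 1.04 with placement within 500 kb, where random summits share the surroundings of the real ones, and lay between 1.46 and 1.59 otherwise. Of 32 list shares, 7 lay outside the random range. The number was 4 at a p of at most 1e-20 and 4 at an FDR of at most 5%, and 5 to 7 otherwise. Of 176 list results that an alternative could change, 158 kept their side of the range, 14 moved into it, 4 moved out of it and 0 changed direction. The share of windows with more regions than random placement, 10.5%, was 7.20% in 500 kb windows and 7.22% at an FDR of at most 5%. The ratio of the median fold at gene ends to that in intergenic sequence, 0.98 (bootstrap interval 0.94 to 1.01), was 1.02 at a p of at most 1e-20 and 1.01 at an FDR of at most 5%. The cause of these shifts was not tested where none is named. Settings that need sequence (CpG counts, a CpG-matched background, repeat content, 300 bp around the summit) were not run. No paired analysis was possible because each group has 1 library.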

Other observations

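The tests in this part were chosen after the values were seen, except that the limit for Y regions at like tag count was set before that ratio was computed, though after their fold had been seen. In a further comparison that partly repeats the fixed lists (Olfr, Vmn and Pcdhb genes), 111 families of protein-coding genes that share a symbol stem, each with at least 20 members, were compared with random lists matched on gene length, and 15 had a region in the gene or within 5 kb more often than the range of those lists and 19 less often. The random lists drew from all protein-coding genes of like length. These include the olfactory and vomeronasal receptor genes, of which 5.06% had a region nearby. Such genes may lower the random share for families of short genes, which was not tested. The families are not a test of any theme, and those named here were picked from both ends of the result. Among those above the range, of 44 genes named Rps, most of them small ribosomal subunit proteins, 26 had a region nearby (59.1%, random median 34.1%, range 22.7 to 45.5), as had 23 of 53 Rpl genes (43.4%, against 24.5%), 26 of 49 Mrpl genes, for the mitochondrial ribosome (53.1%, against 32.7%), and 28 of 32 Cdc genes, many with roles in cell division (87.5%, against 56.3%).

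Among the families below the range, none of 25 Prl genes (prolactin family) and none of 22 Mup genes (major urinary proteins) had a region nearby, against random medians of 36% and 27.3%. A region was found for 1 of 24 Serpina genes (4.17%, against 37.5%), 1 of 33 Rhox genes (3.03%, against 30.3%) and 23 of 99 Cyp genes (23.2%, against 49.5%). Of 44 genes whose symbols begin with Col and a digit, mostly collagens, 23 had one (52.3%, against 72.7%, range 61.4 to 84.1). Each family outside the range stayed outside the range when the random lists were also matched on the number of genes within 500 kb. Many of these families lie in clusters, so their members are not independent. Neither CpG content nor chromosome was matched. X had 0.36 times the regions per Mb of the median autosome, so the low share of the X-linked Rhox genes cannot be told apart from that of their chromosome.

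Regions on the Y chromosome had a larger fold (median 26.1) than those on autosomes (12.1) and fewer tags (median 32 against 104). The autosomal fold matched to the Y regions on tag count had a median of 17.83. Against autosomal regions of like tag count, the fold on Y was still 1.42 times larger (bootstrap interval 1.29 to 1.58). The tag count of the whole region thus went with part of the difference but not all of it. Y regions were also shorter (median 291 bp, against 475 bp for all regions). As the fold is taken at the summit, a like tag count need not mean a like summit height. The bootstrap treats the 332 Y regions as independent. A higher share of male cells in Control than in cKO could raise the fold on Y and lower it on X. The fold of X regions at like tag count was 1.07 times that of autosomal regions (1.02 to 1.12), but this does not decide, because only called regions are listed and matching on Control tags takes out part of such an effect. The number of X regions per Mb, 0.36 times that of the median autosome, does not decide either, as it has no background matched on CpG. Reads shared between repeated Y sequences stay open and were not tested.

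The 5 regions within Uhrf1 were more than its length would give: 0.27% of the 2188 protein-coding genes of its length group (6 genes, Uhrf1 included) held as many. Loss of the targeted DNA itself in cKO cells may lower the cKO signal here without any change in methylation. The median fold of the Uhrf1 regions, 12.68, stood at percentile 53.0 of all regions, and neither the deleted interval nor the share of recombined cells is given in the sources used here, so this cannot be told apart from lower methylation.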
